A study of Mus musculus with 2 samples.

How the data were processed

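The data are gene expression arrays of polysome-associated RNA from bone marrow-derived macrophages of C57BL/6J mice. According to the labels, marrow cells were differentiated for 7 days in medium containing L929 cell supernatant, a source of macrophage growth factor, and then received poly(I:C), a synthetic double-stranded RNA, at 10 µg/ml over 12 h. Lysates were made in the presence of cycloheximide and a mild detergent and were cleared by brief centrifugation. They were then separated on sucrose gradients of 10% to 50%, from which 16 fractions were collected, and RNA of fractions 9 to 11 was labelled and hybridised. There was 1 array from wild-type and 1 array from Oasl1-/- macrophages, grouped by the genotype in the labels. With 1 array per genotype no test between genotypes was possible, and no p-value is given.

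The arrays were Affymetrix Mouse Gene 1.0 ST arrays, on which a probe set covers a whole transcript with several probes along its length. The authors deposited log2 signals for 35556 probe sets per array. Per the submitters' processing notes these are RMA values, a method that corrects background, brings the arrays to a shared distribution and summarises the probes of a set. Scans were processed with GCOS, and Expression Console 1.1 and the R affy package 2.9.2 were named for the comparison, per the series design text. The authors also deposited a log2 ratio and an unsigned fold change for each probe set. The deposited log2 ratio equalled the Oasl1-/- signal minus the wild-type signal in all 35556 rows, so its direction was settled from the values. The deposited fold, a ratio on the linear scale, equalled 2 to the power of the absolute log2 ratio. A second deposited table held the same log2 signals in all 35556 rows for both arrays. Coordinates are those of the file, on build NCBIM37.

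A gene symbol was taken from the annotation column of the table. It gave 25465 probe sets with 1 symbol, 2 with several and 10089 with none, and the latter 2 classes were left out of the gene-level comparison. The 22088 genes were each represented by the probe set with the highest mean log2 signal over the 2 arrays. A gene entered the comparison when the higher of its 2 log2 signals was at least 7. This floor lay close to the upper end of the central 95% of 5222 control probe sets placed in introns, which was 7.13 in the wild-type and 7.34 in the Oasl1-/- array, and it left 7835 genes. Of these, 998 had several probe sets. The RefSeq gene table of assembly GRCm38.p6 was used for names only. It held the accession of 7465 of the 7835 genes, and 726 of these carry another current symbol. Symbols are printed as the array annotation gives them.

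For each gene the log2 difference was the Oasl1-/- signal minus the wild-type signal, and genes with an absolute difference of at least 1, a 2-fold difference, were counted. For 36 gene lists the median difference of the members past the floor was set against 10000 random lists of the same size, matched on mean signal in 20 bins (seed 1). A list counted as outside when its median lay beyond the central 95% of these random lists, and at least 5 members past the floor were required. About 1 in 20 lists falls outside by chance if its members differ independently. Lists whose members vary together may do so more often. The random lists describe these 2 arrays and do not test the genotype. Genes named in the text were those with the 12 largest positive and 12 largest negative differences, 23 genes chosen in advance, the 3 members of each list with the largest absolute difference, and all members past the floor of lists with 5 or fewer. Some genes that this rule takes are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

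The spread of differences was described by the SD and the MAD-based SD over genes, in bins of signal and between probe sets of the same gene. It contains technical and real differences alike and is no replicate error. The number of arrays limits the precision of every value. The procedure was tested on simulated data over 7711 genes, for a simulated comparison of 1 array with 1 array. Differences of single genes had a simulated noise of 0.25 on the log2 scale. The measured SD, which holds real differences too, was wider at 0.39. Changes were planted only in genes whose mean log2 signal was at least 1 above the floor. All 66 genes simulated at 4-fold passed the 2-fold threshold, as did 49.3% of 67 genes at 2-fold and 7.46% of 67 genes at 1.5-fold, while 0 unchanged genes passed. That count of 0 depends on the simulated noise and does not carry over to the measured genes, least of all to dim ones. Of 200 unchanged simulated lists of 20 genes 7.5% lay outside the central 95%, and of 200 lists shifted by 0.3 on the log2 scale 80.5% were found above it. The lists were drawn with wider noise than the single genes, independent from gene to gene.

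The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were floors of 6 and 8 and no floor, the mean over a gene's probe sets, centring on the median gene, removal of a loess trend of difference on mean signal, quantile normalization, a pseudocount of 32 on the linear scale, the second signal table, the deposited log2 ratio, thresholds of 1.5-fold and 3-fold, 10 bins or no matching, list means, and lists without their most different member. Alternatives added after the data were seen were the counts without immune genes, lower thresholds combined with centring, loess or quantile normalization, list members that no other list holds, and random lists matched also on cellular component. A gene was called membrane or secretory when its Gene Ontology component terms in the annotation named a membrane, the endoplasmic reticulum, the Golgi, lysosomes, the cell surface or the extracellular space, and none named mitochondria. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.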

Results

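Polysome-associated RNA was measured on 1 array of wild-type and 1 array of Oasl1-/- bone marrow-derived macrophages, both exposed to poly(I:C) over 12 h. Poly(I:C) is recognised as viral double-stranded RNA and induces type I interferon. OASL1 is an interferon-induced protein of the oligoadenylate synthetase family that is known to restrain translation of IRF7, the transcription factor that amplifies type I interferon production. The comparison asks which mRNAs differ in the polysomal fractions when OASL1 is missing. The polysomal signal of an mRNA depends on its amount and on the share of it that carries several ribosomes, and no array of total RNA was analysed here, so these were not separated. There was 1 array per genotype, so no difference below has a replicate check.

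The 2 arrays had similar signal distributions. RMA brings the arrays to a shared distribution, so this similarity says nothing about the samples. A difference common to all mRNAs would be largely removed, and the differences below are relative to other genes. The median log2 signal over 35556 probe sets was 5.04 in the wild-type and 5.13 in the Oasl1-/- array, with upper quartiles of 7.52 and 7.42. Intron controls, a measure of background, had medians of 3.12 and 3.20. Across the 7835 genes past the floor the Pearson correlation of the arrays was 0.96, over genes that are not independent replicates. The median difference, Oasl1-/- minus wild-type, was -0.09 on the log2 scale, with an SD of 0.39 and a MAD-based SD of 0.32. Removing a loess trend moved this median by 0.11, so small differences of a list are given relative to random lists of like signal and not to 0. The difference between probe sets of the same gene was smaller than the spread over genes. In 603 genes with at least 2 probe sets past the floor the median gap was 0.05, and 96.4% of the gaps were under 0.5. Probe sets of a gene share the hybridisation and may share probes, so a small gap is no measure of replicate error. The 4 polyadenylated spike-in probe sets differed by -0.07 to 0.02 and the 9 hybridisation spike-in probe sets by -0.35 to 0.16.

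Oasl1 signal was lower in the Oasl1-/- array but stayed above background. Its probe set of 29 probes lies at chromosome 5, 115373249 to 115387924, on the plus strand (NCBIM37). The log2 signal was 10.70 in the wild-type and 9.14 in the Oasl1-/- array, a difference of -1.57, which left 33.7% of the wild-type signal. It was the 4th lowest difference of the 7835 genes. The remaining signal exceeded 7.34, the upper end of the central 95% of intron controls on that array. The labels do not give the deleted part of the gene, and a probe outside it would not report the deletion.

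Irf7 was 2.51-fold higher in the Oasl1-/- array, with log2 signals of 10.14 and 11.47 and a difference of 1.33. Its 28 probes lie at chromosome 7, 148449083 to 148452322, on the minus strand. The other interferon regulatory factors differed less. Irf1 differed by 0.56 and Irf2 by 0.42, Irf9, part of the interferon-activated transcription complex, by 0.01, and Irf3, the factor that starts interferon induction, by -0.27. The 7 factors past the floor had a median of 0.07, inside the random range of -0.30 to 0.31, with 1 gene, Irf7, at least 2-fold higher. Type I interferon genes were not measurable. None of the 18 passed the floor, with Ifnb1 at 4.54 and 4.66 and Ifna4 at 3.85 and 4.16 in wild-type and Oasl1-/-.

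**Figure D1:**
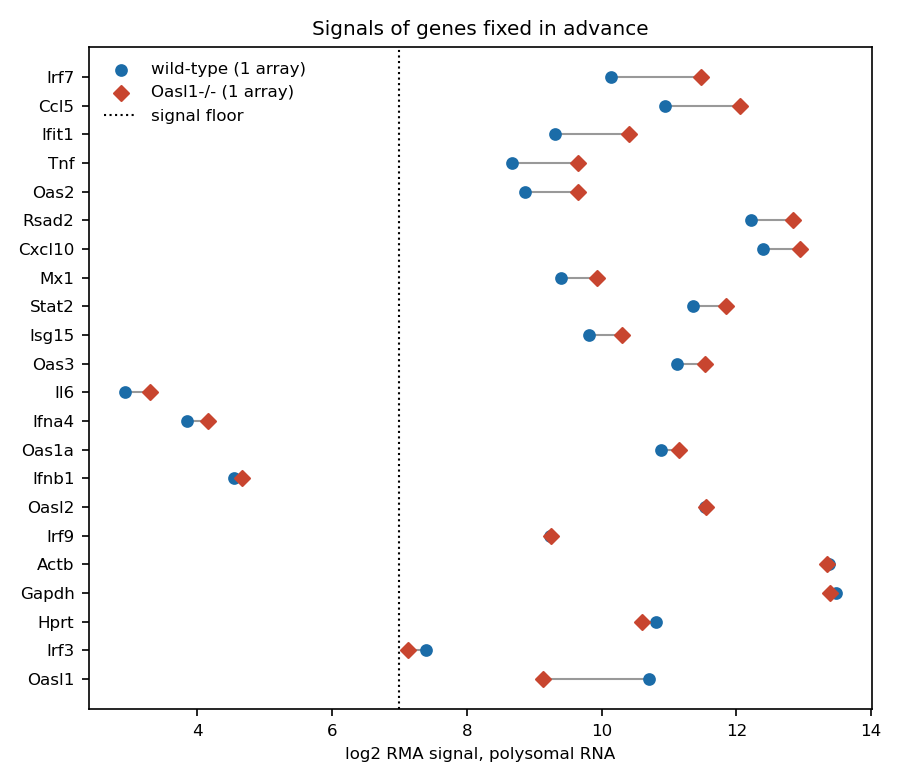
Log2 RMA signals (x axis) of the genes chosen in advance that are reported here (y axis), with 1 wild-type array as circles and 1 Oasl1-/- array as diamonds, ordered by their difference. Irf7 had the largest positive difference, 1.33, Oasl1 the only difference below -1, at -1.57, and Ifnb1, Ifna4 and Il6 lay below the dotted floor of 7 on both arrays.

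In all, 174 genes differed at least 2-fold between the arrays, 2.22% of the 7835 genes. In the Oasl1-/- array 51 of them were lower and the other 70.7% higher, a share that was 82.9% after centring on the median gene, 86.0% after removing a loess trend and 80.4% after quantile normalization. At lower thresholds the direction depended on the scale. On the deposited scale 413 genes were higher and 492 lower at 1.5-fold, and 3062 were higher and 4748 lower by any amount. In counts added after the data were seen, more genes were higher at 1.5-fold after centring (572 against 309), loess (620 against 242) and quantile normalization (514 against 334). By any amount 4106 were higher and 3729 lower after loess, and 3735 and 4095 after quantile normalization. The count of lower genes at 2-fold was 32 after centring, 26 after loess and 25 with a pseudocount of 32. On the dimmer array 36 of the higher and 28 of the 51 lower genes were below the floor, so the size of their differences depends on background. The 11 lists of interferon, cytokine and antigen presentation genes held 165 genes past the floor, of which 23 were at least 2-fold higher and 1, Oasl1, at least 2-fold lower. Without genes of immune lists or immune process terms, a count added after the data were seen, 91 were higher and 49 lower. Of the 174 genes 9 had a second probe set past the floor, and in 6 of these it also differed 2-fold in that direction.

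Among higher genes, the largest difference was that of Enpp4, a membrane-bound nucleotide hydrolase, at 2.32 (5.00-fold), with log2 signals of 6.96 and 9.28. It was followed by Ch25h, the enzyme that makes the antiviral oxysterol 25-hydroxycholesterol, at 2.22 (4.67-fold), by the matrix proteoglycan Vcan at 2.17, by complement factor Cfb at 2.15 and by Nos2, the inducible nitric oxide synthase, at 2.06 (4.17-fold). The chemokine Cxcl9 differed by 2.06, the costimulatory molecule Cd86 by 1.96, the class I gene H2-Q6 by 1.94, the ciliary membrane protein gene Tmem67 by 1.93, the death ligand family members Tnfsf15 and Tnfsf10 by 1.93 and 1.91, and endothelial lipase, Lipg, by 1.90. Vcan, Cxcl9, Tnfsf15 and Enpp4 were below the floor in the wild-type array, where the signal was 6.56, 6.58, 6.54 and 6.96, so their differences and places in this order are uncertain.

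Among lower genes, Uck2, a kinase of pyrimidine salvage, differed by -1.96, with log2 signals of 8.19 and 6.23. Myc, a transcription factor that drives growth and ribosome production, differed by -1.73, and the histone gene Hist1h2ab by -1.67. Next to Oasl1 stood fatty acid synthase, Fasn, at -1.45 (2.73-fold lower), the Ras activator Rasgrp3 at -1.38, Arap2 at -1.37, Dkc1, the pseudouridine synthase of rRNA and telomerase RNA, at -1.34, the coagulation factor subunit gene F13a1 at -1.34, Klhl6 at -1.33, Acat2, which makes acetoacetyl-CoA for sterol synthesis, at -1.33, and the sialyltransferase gene St6gal1 at -1.31. In the Oasl1-/- array 8 of these 12 genes were below the floor, namely Myc at 5.88, Klhl6 at 6.16, Uck2 at 6.23, Dkc1 at 6.44, St6gal1 at 6.53, Arap2 at 6.62, Hist1h2ab at 6.68 and F13a1 at 6.75. Their differences are not well bounded and their order is not settled. With a pseudocount of 32 those of Uck2 and Myc were -1.60 and -1.32. Oasl1, Fasn, Rasgrp3 and Acat2 were above the floor on both arrays.

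**Figure D2:**
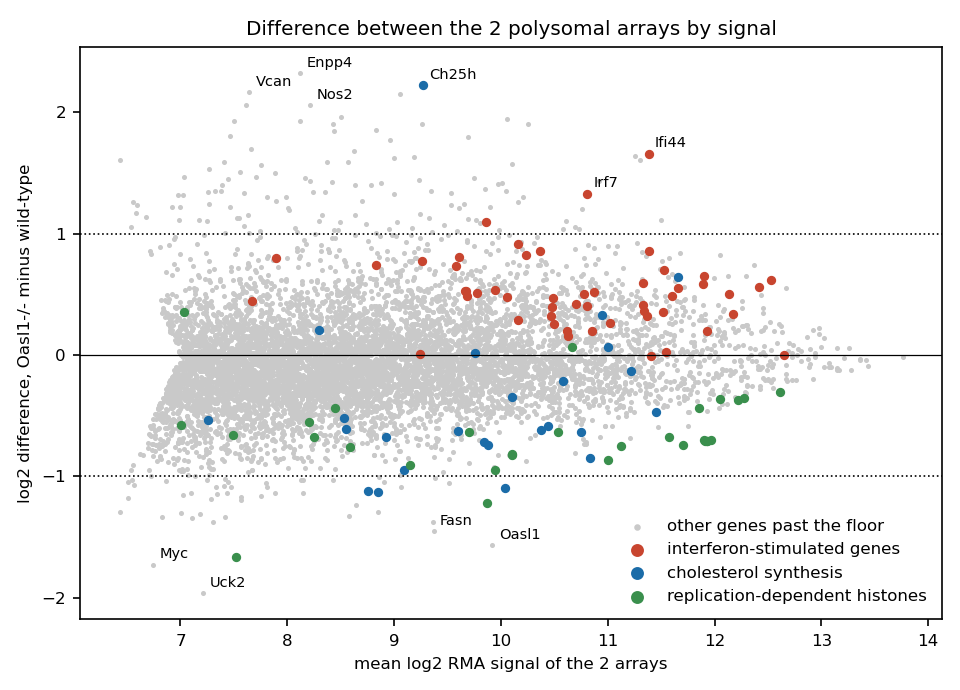
Log2 difference, Oasl1-/- minus wild-type (y axis), against the mean log2 RMA signal of the 2 arrays (x axis) for 7835 genes, 1 array per genotype. Interferon-stimulated genes lie mostly above 0, with a median of 0.50, and cholesterol synthesis and histone genes mostly below, with medians of -0.59 and -0.69, while dotted lines mark a 2-fold difference.

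Antiviral genes induced by type I interferon were higher as a group in the Oasl1-/- array. Of 51 members past the floor 49 were higher by some amount, 3 were at least 2-fold higher and 0 at least 2-fold lower. The median difference was 0.50 (1.41-fold), above the random range of -0.13 to 0.08. Ifi44 differed by 1.66, Irf7 by 1.33 and Ifit1, which binds foreign RNA ends, was 2.14-fold higher. Smaller differences were measured for Rsad2 (0.62), Mx1 (0.52), Isg15 (0.48) and Stat2 (0.48). Rtp4 and Ifitm3, named after their values were seen, were level, with both differences within 0.01 of 0. Interferon-inducible GTPases, which attack pathogen vacuoles, had the highest list median, 0.92 (1.89-fold; random range -0.23 to 0.21). All 12 past the floor were higher, and 4 were at least 2-fold higher, namely Iigp1 at 1.90, Gbp4 at 1.59, Irgm2 at 1.11 and Gbp5, named after its value was seen, at 1.09. These families hold close copies whose probes may be shared, so single members are uncertain.

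The oligoadenylate synthetase family, with Oasl1 itself among its 8 members past the floor, had a median of 0.29 against a random range of -0.27 to 0.26. Oas2 differed by 0.78, Oas1b by 0.69, Oas3 by 0.41 and Oas1a by 0.26, while Oasl2, the closest relative of Oasl1, was level at 0.02. None was at least 2-fold higher and only Oasl1 was at least 2-fold lower. The list mean, 0.10, lay inside its random range, as did the median of 0.26 with a floor of 8. Receptors and adaptors of RNA sensing had a median of 0.32 over 22 members (random range -0.20 to 0.12), with Tlr3, the endosomal receptor for double-stranded RNA, at 1.40, the cytosolic sensor Ifih1 at 0.83 and Tlr7 at 0.68. Tlr3 alone was at least 2-fold higher and none was at least 2-fold lower.

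Inflammatory genes were higher too. The 13 chemokines past the floor had a median of 0.65 (random range -0.22 to 0.19), with 3 at least 2-fold higher, Cxcl9 at 2.06, Cxcl11 at 1.15 and Ccl5 at 1.11, and none 2-fold lower. Cxcl11 was just under 2-fold with a pseudocount of 32. Cxcl10, close to the top of the signal range at 12.39 and 12.94, differed by 0.55. The 12 cytokines had a median of 0.61 (random range -0.31 to 0.16). Tnfsf15, Tnfsf10, Il27 (1.32) and, named after its value was seen, Csf1 (1.32) were at least 2-fold higher and none 2-fold lower. In the wild-type array Il27 was below the floor, at 6.32, so the size of its difference is uncertain. Tnf differed by 0.99, just under the threshold, which it passed after centring, loess or quantile normalization, and Il6 was below the floor at 2.93 and 3.30. The 20 targets and regulators of NF-kB had a median of 0.36 (random range -0.23 to 0.12), with 3 at least 2-fold higher, Nos2, Cd40 at 2.30-fold and the adhesion molecule Icam1 at 1.06, and none 2-fold lower.

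Antigen presentation genes were higher in both classes. All 23 members of the class I list, which holds class I molecules and peptide loading genes, were higher, with a median of 0.48 (random range -0.16 to 0.16). The 3 that were at least 2-fold higher were H2-Q6, H2-gs10, now named H2-Q4, at 1.35 and Tapbpl, a peptide loading factor, at 2.14-fold. Genes of the H2-Q region are near-identical, so H2-Q6 and H2-gs10 are uncertain. The class II list holds class II molecules, loading and costimulation genes. All 10 of its members past the floor were higher, with a median of 0.55 (random range -0.33 to 0.16). The costimulatory gene Cd86 and the class II gene H2-Ab1 (1.07) were at least 2-fold higher, followed by H2-Eb1 at 0.88. None of either list was 2-fold lower.

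Many products in these lists enter the secretory pathway, and genes of that kind were higher outside the immune lists as well. With immune genes left out, 2099 genes with membrane or secretory component terms had a median of 0.09 and 2836 genes with other terms one of -0.17, a split chosen after the data were seen. The class was not uniform. Medians were 0.21 for lysosome, 0.19 for extracellular and 0.14 for endoplasmic reticulum terms, but 0.02 for plasma membrane and 0.01 for Golgi terms. Each lay above its signal-matched random range. Against random lists matched on component as well as signal, the medians of the interferon-stimulated, GTPase, RNA sensing, cytokine, chemokine, NF-kB, class I and class II lists all stayed above the central 95%, as did that of the synthetase family.

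**Figure D3:**
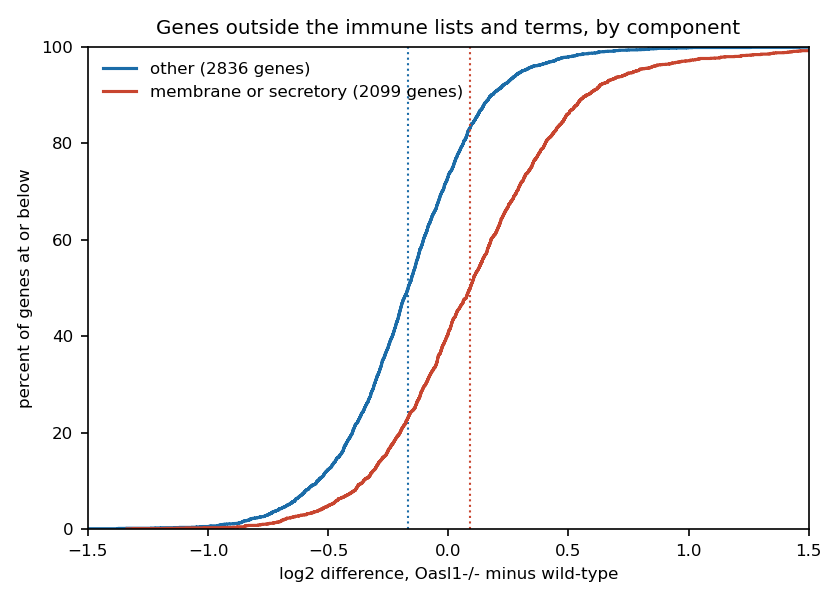
Cumulative percent of genes outside the immune lists and terms (y axis) at or below a log2 difference, Oasl1-/- minus wild-type (x axis; differences beyond it are not drawn), from 1 array per genotype. The curve of 2099 membrane or secretory genes lies to the right of that of 2836 genes with other components, with medians, drawn as dotted lines, of 0.09 and -0.17.

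Endoplasmic reticulum and lysosome genes belong to this class. Genes of the unfolded protein response had a median of 0.18 over 17 members (random range -0.21 to 0.16), with 0 members 2-fold different. Creld2 differed by 0.47, Dnajc3 by 0.42 and the translocon subunit Sec61b by -0.49. This median lay inside the random range once component was matched, and so did the list mean of 0.11. Lysosomal and phagocytic genes had a median of 0.22 over 33 members (random range -0.14 to 0.11), with the receptor kinase Axl at 1.04 as the only one at least 2-fold higher in the deposited signals, Ctsh at 0.93, which passed 2-fold after centring, the osteoclast proton pump subunit gene Atp6v0d2 at -0.87, and none at least 2-fold lower. With component matched, this median stayed above the random range, though close to its upper edge.

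Genes of cell growth and division were lower in the Oasl1-/- array. Cell cycle genes had a median of -0.51 over 29 members (random range -0.24 to 0.06), 28 of them lower. Tyms, the thymidylate synthase, at -1.17 was the only one at least 2-fold lower, Rrm2 differed by -0.84 and Bub1b by -0.71, and none was at least 2-fold higher. Replication-dependent histone genes had the lowest list median, -0.69 over 30 members (1.61-fold lower; random range -0.18 to 0.09), with 28 lower. Hist1h2ab at -1.67 and Hist1h4f at -1.22 were at least 2-fold lower, Hist1h1a differed by -0.95, and none was 2-fold higher. Histone genes share most of their sequence, so single members are uncertain.

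Cholesterol synthesis genes had a median of -0.59 (1.50-fold lower) over 25 members past the floor, against a random range of -0.19 to 0.12. Of these 19 were lower, and 3 were at least 2-fold lower, namely Lss at -1.13, Mvd at -1.12 and, named after its value was seen, Idi1 at -1.10. Each encodes an enzyme of the sterol synthesis pathway. The 1 member that was at least 2-fold higher, Ch25h, hydroxylates cholesterol and does not synthesise it. The cholesterol exporter genes Abcg1 and Abca1, named after their values were seen, differed by 0.65 and 0.33.

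Genes of the translation apparatus were lower by smaller amounts. All 79 cytosolic ribosomal protein genes past the floor were lower, with a median of -0.32 (random range -0.12 to 0.05). Rps27l at -1.14 was the only one at least 2-fold lower, and Rpl22 differed by -0.65. Rps27l was under 2-fold after loess and with a pseudocount of 32. Translation factors had a median of -0.23 over 37 members (random range -0.15 to 0.09), 34 of them lower, with Eif5a at -0.59, Eif2b1 at -0.55 and Eif4a2 at -0.45 and none 2-fold different. Mitochondrial ribosomal proteins had a median of -0.29 over 61 members (random range -0.20 to 0.00), with Mrpl41 the only one at least 2-fold lower, by 2.01-fold, Mrps26 at -0.85 and Mrpl23 at -0.70. Nuclear genes of oxidative phosphorylation had a median of -0.25 over 40 members (random range -0.16 to 0.07), with none 2-fold different, Ndufb3 at -0.61, Atp5g1 at -0.57 and Cox8a at -0.46. Mrpl41 was under 2-fold in all 4 rescaled versions, by centring, loess, quantile normalization or the pseudocount. The medians of these last 2 lists lay inside the random range once component was matched.

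The mitochondrially encoded genes stood opposite. All 8 were higher, with a median of 0.53 (random range -0.26 to 0.27) and none 2-fold different. ND3 differed by 0.75, CYTB by 0.61 and ND4L by 0.60. These mRNAs are made and translated inside mitochondria, so their presence in the gradient fractions is not a measure of cytosolic polysomes.

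**Figure D4:**
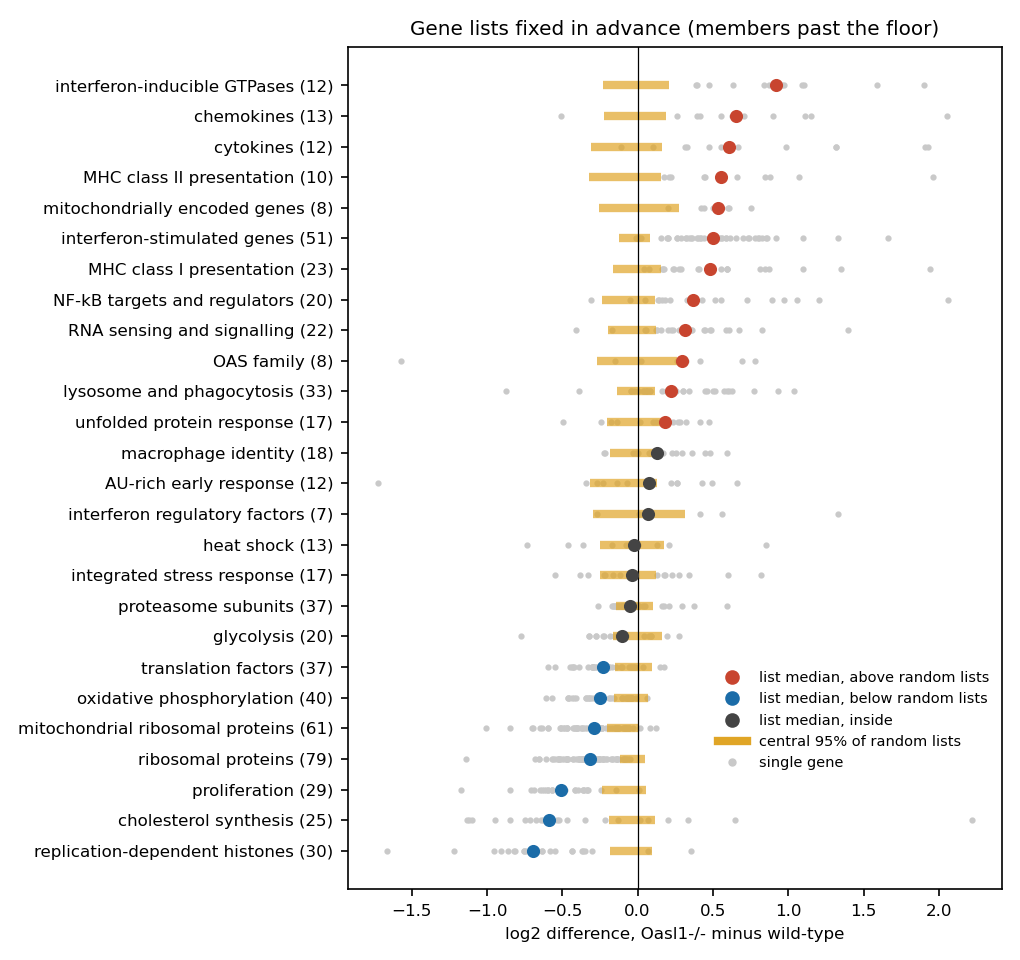
Log2 differences, Oasl1-/- minus wild-type (x axis), of the 26 gene lists with at least 5 members past the floor (y axis, number of members in parentheses), from 1 array per genotype. Grey points are genes, large points list medians and bars the central 95% of 10000 signal-matched random lists. Of the 26 medians 12 lie above, 7 below and 7 inside their bar.

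The remaining lists with enough members were inside their random range. The integrated stress response had a median of -0.04 over 17 members (random range -0.25 to 0.12), with Asns at 0.82, Phgdh at 0.60 and Shmt2 at -0.55. Heat shock genes had one of -0.02 over 13 members (-0.25 to 0.18), with Hspa1a at 0.86, Hspe1 at -0.73 and Hspd1 at -0.46. Proteasome subunits had one of -0.05 over 37 members (-0.14 to 0.10), with the immunoproteasome subunit gene Psmb10 at 0.60, Psma5 at 0.37 and Psmd10 at 0.30. The sign of these 3 medians turned after centring and after loess, and with no floor the integrated stress response median of 0.11 lay above its random range. Glycolysis genes had a median of -0.11 over 20 members (-0.16 to 0.16), with Pdk1 at -0.77 and Gpi1 and Hk2 both at -0.32. None of these 4 lists held a gene 2-fold different. The probe sets taken for Hspe1, Hspd1 and Gpi1 may lie at copies, so the values of these genes are uncertain. Immediate early genes had a median of 0.08 over 12 members (-0.32 to 0.13). Myc was 2-fold lower, Zfp36 differed by 0.66 and Dusp1 by 0.50, none was 2-fold higher, and without Myc the median of 0.22 lay above the random range. Of the 26 lists 19 lay outside the central 95%, against 1.3 expected if members differed independently of each other. Members of a list may vary together between any 2 cultures, so this excess is no evidence for the genotype.

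Macrophage identity genes were close to level. The median was 0.13 over 18 members (random range -0.18 to 0.16), with none 2-fold different, Mertk at 0.59, Cd14 at 0.48 and Fcgr1 at 0.45. Markers of other cell types were mostly below the floor. Of 20 lymphocyte markers none passed, of 18 neutrophil markers Csf3r (1.11) and Padi4 (-0.29), of 16 dendritic cell markers Bst2 (0.34), which is also interferon-stimulated, and Tcf4 (-0.07), of 13 mast cell and basophil markers Hdc (1.02), and of 17 stromal, erythroid and platelet markers Pf4 (-0.30). With a pseudocount of 32 Csf3r and Hdc were under 2-fold. Of 17 genes of alternative macrophage activation 4 passed, Clec10a (-0.59), Mrc1 (-0.39), Tgm2 (0.35) and, named after its value was seen, Il4ra (0.02). The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty lay between -0.15 and 0.08, and Xist was at 3.02 on both arrays.

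RNAs that are not translated were mostly close to background. Of 65 small nucleolar and Cajal body RNAs only Scarna17 passed the floor, with a difference of 0.37, and of 3 nuclear-retained RNAs only Malat1, at 6.95 and 7.27, while Meg3 was at 4.54 and 5.13. Among reference genes Actb differed by -0.03, Gapdh by -0.09 and Hprt by -0.20, and the sign of Actb turned after centring, loess and quantile normalization.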

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

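The values in this part come from probe sets that the comparison of genes did not use, and all of its tests were chosen after the data were seen. Of 187 intron control probe sets past the floor 4 were at least 2-fold higher in the Oasl1-/- array and 0 lower. Of 1045 exon control probe sets past the floor, which target normalization genes, 4 were at least 2-fold higher and 11 lower, with a median of -0.08. Of 314 other probe sets past the floor without a gene symbol 2 were at least 2-fold higher and none lower. Probe set 10608646, annotated as similar to an interferon-inducible GTPase, differed by 1.51, with log2 signals of 7.47 and 8.97. Probe set 10361133, on chromosome 1 and without annotation, differed by 1.11, with signals of 6.45 and 7.57.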

How the results depend on the processing

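No paired analysis was possible because each genotype had 1 array, which also left no replicate to leave out. The second signal table and the deposited log2 ratio equal the main values, so they tested nothing and are left out of the tallies here, as is centring for single genes, which moves all alike by less than any bin's spread. Of 363 list medians recomputed under the other alternatives 338 kept their sign and their side of the random range, though centring could change only the sign. Loess could hardly change the side, because the random lists are matched on signal. Of 378 values of named genes 370 moved by less than the spread of their signal bin or, for genes below the floor, which have no bin, the widest bin spread (0.40). The other 8 were 5 genes below the floor after loess (Ifna4, Ifnb1, Il6, Meg3 and Xist) and Myc, Uck2 and Vcan with the pseudocount. Random lists matched on component were added after the data were seen, as were the counts without immune genes, 1.5-fold counts after rescaling and members that no other list holds. The causes of the shifts below were not tested unless stated. The count of genes higher in Oasl1-/- was 413 at 1.5-fold and 29 at 3-fold on the deposited scale, and 91 to 160 under the other alternatives at 2-fold. The count of lower genes, 51, was 492 at 1.5-fold, 3 at 3-fold, 77 with no floor, 29 with a floor of 8, 32 after centring, 26 after loess and 25 with a pseudocount of 32, which shrinks dim genes by construction. The integrated stress response median turned positive with no floor (0.11, above its random range of -0.20 to 0.10) and, inside the range, with a floor of 8 (0.046), centring (0.054), loess (0.075), quantile normalization (0.039) and as a mean (0.040), and was 0.00 with a floor of 6. Heat shock turned positive with centring (0.065), loess (0.057) and quantile normalization (0.0032), and the proteasome with centring (0.042) and loess (0.033). Immediate early genes lay above the random range with floors of 6 (0.13) and 8 (0.24), without Myc (0.22) and with component matched (0.078), and their mean was -0.036. Glycolysis lay below it as a mean (-0.12), and macrophage identity lay above it with no matching (0.13). The synthetase family was inside it with a floor of 8 (0.26) and as a mean (0.10), the unfolded protein response as a mean (0.11) and with component matched (0.18), and oxidative phosphorylation (-0.25) and mitochondrial ribosomal proteins (-0.29) with component matched. Genes near the floor are limited by background. More genes were higher than lower at 2-fold and 3-fold, and at 1.5-fold fewer were on the deposited scale but more after centring (572 against 309), loess (620 against 242) and quantile normalization (514 against 334).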

Other observations

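The tests of signal-dependent bias on the interferon-stimulated genes, of other cell types and of the cholesterol list, and the scan of process terms, were chosen after their results had been seen. Among 223 Gene Ontology process terms with 15 to 200 genes past the floor, 43 had medians above and 27 below signal-matched random lists. By chance 11.15 would lie outside if genes differed independently, but genes of a term may vary together and the terms overlap. The 52 genes of rRNA processing had a median of -0.34 and the 46 of ribosome biogenesis one of -0.33, with Nop58 at -0.80, Fbl at -0.74 and Ncl at -0.35. The 30 genes of fatty acid biosynthesis had a median of -0.29, and Fasn at -1.45, Elovl6 at -1.30 and the acyl-CoA synthetase gene Acsl3 at -1.14 were all at least 2-fold lower, while Ch25h at 2.22, which this term also holds, was the 1 at least 2-fold higher. Nop58, Elovl6 and Acsl3 were below the floor in the Oasl1-/- array, at 6.67, 6.35 and 6.77, so the size of their differences is uncertain. Single genes of polyamine synthesis, for which no list was tested, were Srm at -1.29, Amd1 at -1.14 and Odc1 at -0.55. DNA replication (71 genes) had a median of -0.28. Genes in this part outside the naming rule were chosen after their values were seen.

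On the higher side, the 103 cell adhesion genes had a median of 0.18 (random range -0.14 to 0.01), with 11 at least 2-fold higher and none lower, among them F11r at 1.80, Eng at 1.42 and Vcam1 at 1.35. Since 82 of them have a membrane or secretory term, random lists matched also on component came closer, at -0.02 to 0.14. Complement C3 differed by 1.61 beside Cfb, the checkpoint ligand Cd274 by 1.57, the vascular growth factor receptors Flt1 and Kdr by 1.56 and 1.41, and the matrix proteases Mmp14, Mmp25 and Mmp13 by 1.59, 1.51 and 1.33. In the wild-type array F11r, Vcam1, Mmp25 and Flt1 were below the floor, at 6.56 to 6.97, so the size of their differences is uncertain. The 18 genes of GPI anchor biosynthesis, none of them in a preset list, had a median of 0.34 (random range -0.27 to 0.09), with Pigs at 0.79. All 18 have a membrane or secretory term, and with component matched the random range was -0.13 to 0.31. The zinc ion transport median of 0.25 lay inside that kind of range (-0.14 to 0.31). ND5 and ND6, which carry no symbol in the table, differed by 0.85 and 0.71 like the other mitochondrial mRNAs. Mitochondrial rRNAs were level, at -0.04 for s-rRNA and 0.06 for 16S. Their wild-type and Oasl1-/- signals, 13.00 and 12.96 for s-rRNA and 12.78 and 12.83 for 16S, lay close to the top of the signal range. Differences may be compressed there, so these values do not settle whether the rRNAs and mRNAs of mitochondria differ in their response.

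The first pattern weighed is the higher signal of interferon-stimulated genes. Their median of 0.50 lay above random lists matched on signal (-0.13 to 0.08), which argues against a bias that follows signal. After loess it was 0.58, above -0.05 to 0.16. Loess moves the list and its matched lists nearly alike, so this adds no separate test. The 26 members with no membrane or secretory term had a median of 0.49, above -0.17 to 0.13, which argues against recovery of membrane-bound polysomes as the cause. At most 12.5% of any list of neutrophil, dendritic, lymphocyte, mast or stromal cell markers reached the floor in the Oasl1-/- array. They were 6 of 84 in all, with Csf3r at a difference of 1.11 and Hdc at 1.02 among them. This argues against a large share of these cells, but a small share might not reach the floor and stays open. Over all markers on the array, most of them below the floor, more were higher than lower in each list. The counts ran from 10 against 6 stromal, erythroid and platelet markers to 15 against 3 lymphocyte markers. Background leaned the same way, with a median difference of 0.09 over 45 antigenomic control probe sets and 0.06 over 5222 intron controls. These counts therefore do not separate a small share of such cells from background. Endothelial cells and others stay open too. Of 25 endothelial markers 24% reached the floor. Kdr, Flt1, Eng, Vcam1 and Lipg were put in that list after they were seen to differ. Beside them only Vwf reached it, at 0.29, so the share decides nothing. A difference between cultures unrelated to genotype cannot be told apart from the genotype with 1 array each, and whether mRNA amount or polysome loading differed stays untested.

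The second pattern is a split of genes by component, since outside the immune set 2099 membrane or secretory genes had a median of 0.091 against a random range of -0.09 to -0.06, and 2836 genes with other components had -0.17. Better recovery of membrane-bound polysomes from the Oasl1-/- lysate would give these values, but they are the pattern itself and no separate test bears it out. Bias that follows signal is argued against by the median of 0.091, since the random lists below it are matched on signal. The median of 0.19 after loess (random range 0.01 to 0.04) adds no separate test, because loess moves both nearly alike. Recovery does not account for the cholesterol synthesis genes, since 19 of 25 have a membrane term and their median was -0.59, below -0.19 to 0.11. Recovery of the other membrane genes and their regulation in Oasl1-/- cells cannot be told apart, with 1 lysate per genotype.

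The third pattern is the Oasl1 signal that stays in the Oasl1-/- array. At 9.14 it lay above 7.34, the upper end of the central 95% of intron controls, which argues against array background. The annotation does not mark this probe set for cross-hybridisation, but it marks only 19 of 35556 probe sets, so this says little about that source. Transcript from the targeted allele and cross-hybridisation from a related mRNA still cannot be told apart, since the 29 probes are summarised to 1 value per array. No biological explanation was tested.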
